A study of Homo sapiens with 12 samples.

How the data were processed

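RNA was measured in 2 human breast cancer cell lines, MDA-MB-231 (estrogen receptor negative) and MCF7 (estrogen receptor positive). Cells were kept for 24 h in medium with serine (+Ser) or without it (-Ser), and per the series design each of the 4 groups holds 3 biological replicates, which gives 12 libraries. Per the labels' protocols, RNA was harvested from adherent cultures with Trizol and libraries followed standard Illumina protocols. Kallisto 0.42.4, sleuth and the hg19 build are named in the submitters' processing notes, and the transcript set is not stated.

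Each sample came with a table of the authors' kallisto values per transcript, which per the file headers holds estimated counts and TPM, an abundance scaled to transcript length and library size. The authors also deposited 1 gene table per line that is named as raw counts but holds TPM. The sums of those deposited columns were 811276 to 910952, and in each library 98.4% to 98.8% of the 26627 gene symbols found in both sources lay within 1% of the gene sum of the kallisto TPM. Dates had replaced 26 of the gene names. The tests planned for the gene tables need counts, so they were run on the authors' estimated counts instead. This had been set down as an alternative and became the main source, and the deposited TPM tables became an alternative chosen after seeing the data.

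Estimated counts were summed per gene symbol and rounded to whole numbers. The map was the primary assembly annotation of GENCODE v29 (GRCh38), in which 145204 of the 176981 transcripts (82.0%) had an entry. The mapped transcripts held 89.0% to 91.2% of the estimated counts of a library and gave 36662 symbols. The libraries held 19042846 to 25961974 estimated counts, of which 17319039 to 23666676 lay on named genes. Coordinates are those of GENCODE v29 on GRCh38, not of the authors' hg19. Kallisto divides reads among similar transcripts, so values of near-identical gene copies are uncertain.

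Low genes were removed with edgeR's filterByExpr, libraries were scaled by TMM, and genes were tested with edgeR 4.0.16 (quasi-likelihood F test, R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are counts scaled to the TMM-adjusted library sizes of the fit they are printed with, and standard errors (SE) come from the F statistic. The comparisons were -Ser against +Ser in each line (6 libraries each), the difference of the 2 responses (the interaction in a fit of all 12 libraries), and MDA-MB-231 against MCF7 in +Ser medium from that same fit. The overlap of the lines' changed genes was tested with Fisher's exact test. The lines share no control library.

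In all, 27 gene lists were fixed before the data were examined and tested with camera (limma 3.58.1), 2-sided, with a preset correlation of 0.01 between genes, for lists with at least 3 tested genes. The named genes followed a rule fixed at the same time. It took the 5 serine and glycine synthesis genes, then per line the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups, and up to 4 members per list by smallest p. For the difference between the lines it took the 5 largest in each direction at a mean of at least 5 CPM. For the +Ser comparison it took up to 6 members each of 3 lists: serine, luminal, and basal and mesenchymal. The last of these is also called the basal list or basal markers below. Genes outside this rule are named as such.

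Alternatives fixed at the same time were DESeq2 size factors, library size only, DESeq2 1.42.0, limma-voom, no filter beyond a total of 1 count, a mean of at least 5 CPM, a log2 fold change of at least 1, the replicate number as a block, all 4 groups in a shared fit, fry in place of camera, camera with an estimated correlation, and each library left out. Alternatives added after seeing the data were the deposited TPM with limma (a pseudocount of 1 and a mean TPM of at least 1), each library's trend on transcript length and GC content removed as an offset (lowess span 0.3), and the omission of the MDA-MB-231 libraries +Ser 3 and -Ser 1 together. The gene tests and list tests were tested on simulated data with 200 changed genes. In the simulation of MDA-MB-231 (14037 genes), edgeR recovered 5.97% of 1.5-fold, 47.8% of 2-fold and 84.8% of 4-fold changes. In that of MCF7 (15882 genes) the shares were 52.2%, 74.6% and 87.9%, and in that of the interaction (16581 genes) 1.49%, 44.8% and 71.2%. Of the calls in these simulations 8% in MDA-MB-231, 6.54% in MCF7 and 4.88% in the interaction were false, against a nominal 5%. Each comparison had a single simulated run, so these shares do not measure an excess over 5%. Far more genes were called in the data (37.4% in MDA-MB-231, 50.7% in MCF7 and 24.3% in the interaction). The adjustment was therefore stricter in the simulation, and its recovery shares may understate those in the data. Transcripts with no entry in the primary assembly annotation of GENCODE v29 (31777) were left out of the gene tests and fitted separately. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.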

Results

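Transcript levels were measured by RNA sequencing in MDA-MB-231 and MCF7 breast cancer cells after 24 h with or without serine, with 3 biological replicates in each of the 4 groups. The MDA-MB-231 libraries held 21018856 to 25961974 estimated counts and the MCF7 libraries 19042846 to 24739133. The question, per the series title, was how transcription changes after acute serine starvation, and the design asks it in a line without and a line with the estrogen receptor. In principal components of log2 CPM, the first component separated -Ser from +Ser in both lines and held 65.8% of the variance in MDA-MB-231 and 58.2% in MCF7. Replicates were less alike in MDA-MB-231, where the common biological coefficient of variation was 0.201 against 0.0729 in MCF7.

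The genes changed by serine starvation in MDA-MB-231 numbered 5345 of 14286 tested at an edgeR adjusted p under 0.05, 2654 higher and 2691 lower in -Ser, and 2301 of them changed at least 2-fold. In the deposited TPM tables tested with limma 38.1% of the calls were higher, against 49.7% here, and the median log2 fold change of all genes was -0.11 against 0.01. The groups did not overlap in 51.0% of genes, where chance gives 10%. Without the libraries +Ser 3 and -Ser 1, which stood apart on the second component, 7727 genes were called. Leaving out single libraries moved the count most without +Ser 2 (3535 genes), -Ser 2 (3416) and -Ser 3 (3028). The share of mitochondrially encoded mRNA was 0.520% to 1.19% in +Ser and 0.756% to 2.23% in -Ser, and that of ribosomal protein genes 3.26% to 4.51% and 3.72% to 7.43%, so these shares varied between replicates as well as between groups. The trend of a library on transcript length is Spearman's rho across genes with the deviation from the group's mean. This trend ran from -0.473 to 0.356 in +Ser and from -0.513 to 0.519 in -Ser, against -0.118 to 0.125 over the MCF7 libraries. The log2 fold changes in MDA-MB-231 had a rho of -0.26 with length (0.01 in MCF7). On GC content the trend ran from -0.245 to 0.156 over the MDA-MB-231 libraries and from -0.182 to 0.245 over the MCF7 libraries. With GC content the log2 fold changes had a rho of -0.21 in MCF7 and 0.04 in MDA-MB-231.

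Of the 5 serine and glycine synthesis genes, 4 rose and 1 fell in MDA-MB-231 (n = 3 per group, edgeR adjusted p). PHGDH (ENSG00000092621.12, GRCh38 chromosome 1, 119648411 to 119744226) rose from 18.2 ± 2.0 (SD) to 38.4 ± 2.37 CPM, a log2 fold change of 1.08 with an SE of 0.13 and an adjusted p of 0.000926. PSAT1 (ENSG00000135069.13, chromosome 9, 78297143 to 78330093) rose from 111 ± 17.2 to 294 ± 26.7 CPM, PSPH (ENSG00000146733.13, chromosome 7, 56011051 to 56051604) from 35.3 ± 2.29 to 74.2 ± 5.70, and SHMT2 (ENSG00000182199.10, chromosome 12, 57229327 to 57234935) from 265 ± 22.4 to 678 ± 35.0. Their log2 fold changes were 1.40, 1.07 and 1.36. SHMT1 (ENSG00000176974.19, chromosome 17, 18327860 to 18363563) fell from 39.0 ± 6.93 to 19.9 ± 1.76 CPM, a log2 fold change of -0.97. All 5 were also called when adjusted over the list alone.

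In MCF7 the same 4 genes rose and SHMT1 fell. PHGDH rose from 40.2 ± 2.90 to 179 ± 7.68 CPM, a log2 fold change of 2.15 with an SE of 0.06 and an edgeR adjusted p of 9.83e-11. PSPH rose from 21.6 ± 0.940 to 39.7 ± 1.57 CPM and SHMT2 from 175 ± 5.13 to 317 ± 8.03, while SHMT1 fell from 94.1 ± 5.69 to 67.0 ± 3.01. PSAT1 was near the floor, with 10 counts over the 3 +Ser libraries and 56 over the 3 -Ser libraries (0.159 ± 0.141 and 0.973 ± 0.106 CPM, edgeR adjusted p 0.00559). All 5 were called when adjusted over the list alone.

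**Figure D1:**
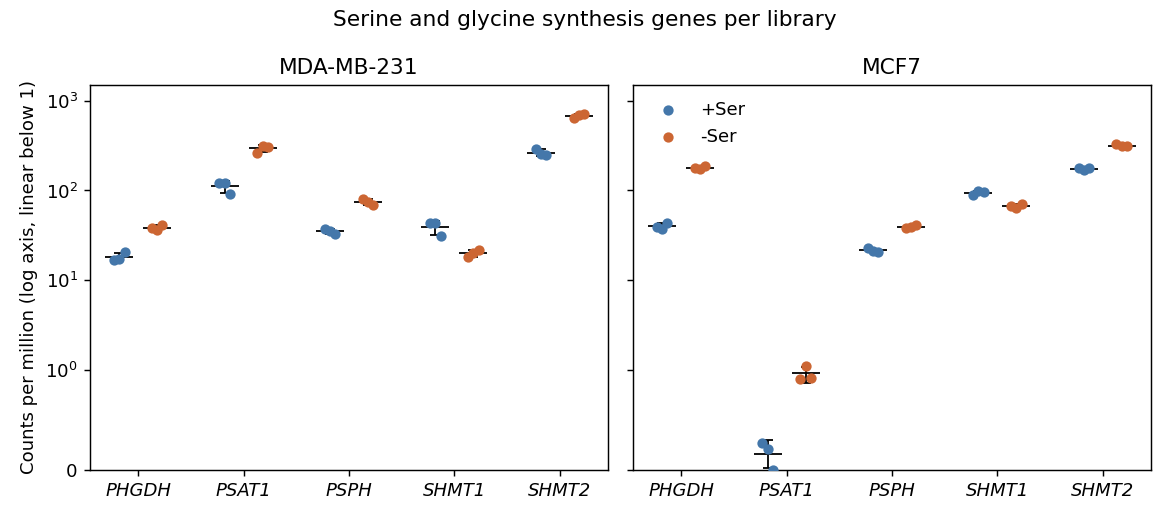
Counts scaled to library size (CPM, log axis, linear below 1) of the 5 serine and glycine synthesis genes in each of 12 libraries, with the mean (line) and SD (bar) of 3 replicates. PSAT1 lies at 111 and 294 CPM in MDA-MB-231 and at 0.159 and 0.973 CPM in MCF7.

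The ATF4 targets of the integrated stress response rose most in MDA-MB-231: 26 of 28 tested members were higher and 1 lower (27 called adjusted over the list alone), with a median log2 fold change of 2.02 and a camera adjusted p of 2.52e-38. TRIB3 rose from 18.2 to 277 CPM, CTH from 6.20 to 86.1 and SESN2 from 12.4 to 76.1. In the same line 13 of 20 cytosolic aminoacyl-tRNA synthetases were higher and 3 lower (18 adjusted over the list alone, camera adjusted p 8.96e-05, 0.21 with an estimated correlation between genes), with SARS rising from 208 to 908 CPM. Of the amino acid transporters 9 of 22 were higher and 6 lower (17 adjusted over the list alone, camera adjusted p 0.024, estimated correlation 0.414), among them SLC6A9 and SLC1A4 higher. Autophagy and lysosome genes (14 higher, 2 lower of 22, adjusted over the list alone 16, camera adjusted p 1.23e-06, estimated correlation 0.275) rose with MAP1LC3B at 47.6 and 335 CPM. NF-kB inflammatory genes (12 higher, 2 lower of 18, adjusted over the list alone 16, camera adjusted p 8.6e-05, estimated correlation 0.245) rose with ICAM1 at 23.3 and 78.5 CPM.

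Lists that fell in MDA-MB-231 were those of division, of lipid and nucleotide synthesis, and of glycolysis. DNA replication genes were lower for 28 of 29 members (28 adjusted over the list alone), with a median log2 fold change of -1.42 and a camera adjusted p of 4.66e-25, and RRM2 fell from 342 to 65.6 CPM. Mitosis genes were lower for 26 of 30 (26 adjusted over the list alone, median -1.54, camera adjusted p 3.52e-25), with KIF20A falling from 206 to 35.5 CPM. Cholesterol synthesis (12 lower of 24, adjusted over the list alone 15, camera adjusted p 3.38e-05, estimated correlation 0.232) and fatty acid synthesis (9 lower, 1 higher of 14, adjusted over the list alone 10, camera adjusted p 9.48e-05, estimated correlation 0.319) fell with DHCR24 at 391 and 62.1 CPM and FADS2 at 253 and 67.4 CPM. Glycolysis (10 lower of 20, adjusted over the list alone 10, camera adjusted p 0.00212, estimated correlation 0.245) and purine and pyrimidine synthesis (10 lower, 1 higher of 18, adjusted over the list alone 14, camera adjusted p 0.00476, estimated correlation 0.167) fell with LDHA and CTPS1.

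The other called lists in MDA-MB-231 were serine and glycine synthesis (median 1.08, camera adjusted p 0.00373, estimated correlation 0.167), NRF2 and glutathione (9 higher, 3 lower of 22, camera adjusted p 0.009, estimated correlation 0.458) and replication-dependent histones (4 higher, 1 lower of 9, camera adjusted p 0.0312, estimated correlation 0.508), which makes 14 of 27. With an estimated correlation between genes, only ATF4 targets (adjusted p 0.0233), DNA replication and mitosis (both 0.0448) kept their calls in MDA-MB-231. The transporters also lost their call without +Ser 1, +Ser 2 or -Ser 1 (camera adjusted p 0.0794, 0.052 and 0.0522), and the histones without +Ser 2 (0.101).

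Lists not called in MDA-MB-231, with their median log2 fold changes, were folate metabolism (0.08), sphingolipid synthesis (-0.10), endoplasmic reticulum chaperones (-0.02), p53 targets (-0.06), estrogen response (-0.39), hypoxia (-0.18), interferon-stimulated genes (-0.11), polyamine and methionine cycle (-0.01), extracellular matrix (-0.13), luminal markers (-0.55), basal markers (-0.14), fibroblast, endothelial and immune markers (0.20) and mitochondrially encoded mRNAs (0.60). For the folate, chaperone, p53, hypoxia, polyamine, matrix and fibroblast lists the median and either the mean or the direction of the test differed in sign. Under the deposited TPM the medians of the folate, matrix and fibroblast lists changed sign, and with library size only those of the chaperone and polyamine lists.

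The largest rises in MDA-MB-231 were NUPR1 (1.12 ± 0.581 to 65.7 ± 26.8 CPM), GDF15 (4.56 ± 1.56 to 209 ± 50.2), IL24, HKDC1, LAMP3, ADM2, LURAP1L, CHAC1, MMP1 and TRIB3. The largest falls were AL355075.4, DMBT1, ARTN, NEURL1B, SHROOM2 (41.2 ± 6.03 to 4.69 ± 1.25 CPM), ARSI, MKI67, E2F2 (26.0 ± 2.11 to 3.54 ± 1.01), CASZ1 and HHIP. Some of these falls were enlarged by +Ser 3, where AL355075.4, DMBT1 and NEURL1B were at 25.1, 20.8 and 77.1 CPM. The other +Ser libraries had at most 7.08, 10.7 and 43.4 CPM for them. ARTN, in contrast, was lowest in +Ser 3 (7.20 CPM). Among these 20 the edgeR adjusted p-values ran from 7.44e-05 for TRIB3 to 0.00392 for MKI67, whose +Ser mean of 1254 CPM had an SD of 790.

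In MCF7, 8228 of 16229 tested genes changed at an edgeR adjusted p under 0.05, 4073 higher and 4155 lower, and 1458 changed at least 2-fold. The deposited TPM tables gave 60.0% higher calls, against 49.5% here. The groups did not overlap in 58.2% of genes, where chance gives 10%. The larger count than in MDA-MB-231 goes with a smaller spread, since the median SE was 0.100 against 0.195, and among genes with a mean of at least 5 CPM an absolute log2 fold change of at least 1 was seen for 6.81% in MCF7 and 14.8% in MDA-MB-231.

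ATF4 targets rose in MCF7 as well, 26 higher and 3 lower of 30 (29 adjusted over the list alone), with a median log2 fold change of 1.52 and a camera adjusted p of 1.25e-59. ASNS rose from 47.7 to 309 CPM and VEGFA from 64.1 to 275. Synthetases (15 higher, 3 lower of 20, adjusted over the list alone 19, camera adjusted p 1.6e-41) rose with SARS at 190 and 920 CPM, and transporters (12 higher, 3 lower of 22, adjusted over the list alone 15, camera adjusted p 6.59e-14) with SLC7A5 at 193 and 1289.9 CPM. The p53 targets (18 higher, 1 lower of 22, adjusted over the list alone 20, camera adjusted p 1.99e-13) rose with CDKN1A at 160 and 424 CPM. Interferon-stimulated genes (18 higher of 22, adjusted over the list alone 18, camera adjusted p 5.49e-06) rose with STAT1 at 197 and 295 CPM and IFIH1 at 10.5 and 30.7. Histones (9 higher of 12, camera adjusted p 5.93e-08) rose with HIST1H2AC, and histone copies share reads.

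DNA replication genes fell in MCF7 for 28 of 29 members (28 adjusted over the list alone, median -1.28, camera adjusted p 3.89e-45), with TK1 at 158 and 47.8 CPM. Mitosis genes fell less (23 lower, 1 higher of 30, adjusted over the list alone 24, median -0.47, camera adjusted p 3.42e-11). Cholesterol synthesis (16 lower, 2 higher of 23, adjusted over the list alone 18, camera adjusted p 2.48e-10) and fatty acid synthesis (12 lower, 1 higher of 14, adjusted over the list alone 13, camera adjusted p 2.43e-07) fell with FDPS and SCD. Glycolysis fell (16 lower, 3 higher of 20, adjusted over the list alone 19, camera adjusted p 4.24e-07, estimated correlation 0.0967), with GAPDH at 2930 and 1306 CPM and PKM at 1416 and 670, while HK2 rose from 52.5 to 121. Mitochondrially encoded mRNAs fell (12 of 13, camera adjusted p 4.1e-06, estimated correlation 0.25), and their share was 5.35% to 5.50% in +Ser and 4.25% to 4.68% in -Ser.

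The remaining called lists in MCF7 were serine and glycine synthesis (median 0.88, camera adjusted p 5.49e-06), NF-kB genes (7 higher of 9, 0.0143), autophagy (13 higher, 3 lower of 22, 0.00495), estrogen response (14 higher, 5 lower of 26, 0.0161), luminal markers (4 higher, 7 lower of 15, 0.00495) and endoplasmic reticulum chaperones (3 higher, 8 lower of 18, 0.0113), which makes 18 of 27. The medians of the luminal and chaperone lists were -0.07 and -0.00455, and both turned positive under the deposited TPM. With an estimated correlation 11 lists kept their calls. The 7 that did not had adjusted p-values of 0.0967 (glycolysis), 0.132 (NF-kB), 0.17 (autophagy), 0.18 (estrogen), 0.201 (chaperones), 0.237 (luminal) and 0.25 (mitochondrial). Lists not called in MCF7 were folate metabolism (median 0.18), sphingolipid synthesis (0.03), NRF2 and glutathione (-0.04), hypoxia (-0.04), purine and pyrimidine synthesis (-0.21), polyamine (0.10), extracellular matrix (0.09), basal markers (0.67) and fibroblast, endothelial and immune markers (0.05). The median and mean of the NRF2, hypoxia and fibroblast lists differed in sign, and the NRF2 and fibroblast medians changed sign under the deposited TPM.

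**Figure D2:**
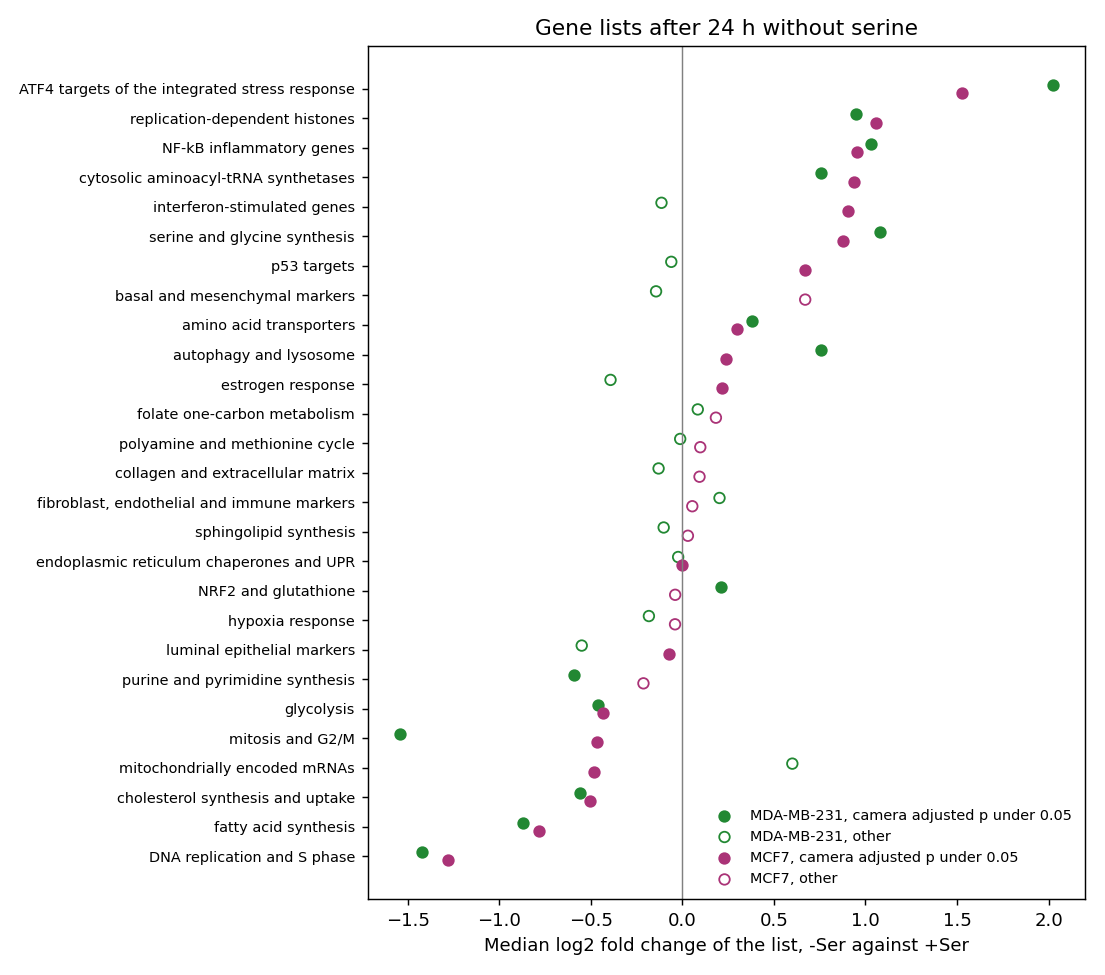
Median log2 fold change (-Ser against +Ser) of each of the 27 gene lists in both lines, filled where the camera adjusted p was under 0.05. ATF4 targets have the highest medians (2.02 and 1.52), and DNA replication lies at -1.42 and -1.28.

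The largest rises in MCF7 were SFT2D3, DMGDH, SLC7A11 (6.82 ± 0.487 to 108 ± 5.91 CPM), CHAC1, ADM2, PSG9, CAPN8, BDKRB2, DDIT3 (7.46 ± 0.574 to 53.2 ± 0.855) and RGPD6. The largest falls were NES (21.4 ± 1.62 to 1.34 ± 0.377 CPM), FSD1, KCNH2, NRM, GPRIN1, KIF3C, PANX2, NDRG2, PPFIA4 and LHX2. Among these 20 the edgeR adjusted p-values ran from 7.49e-12 for SLC7A11 to 4.5e-05 for PPFIA4. PSG9 and RGPD6 have near-identical copies and SFT2D3 overlaps another gene, so their values are uncertain, and SFT2D3 lost its call in DESeq2. There the log2 fold change of SFT2D3 in MCF7 had an adjusted p of 0.0506, where the alternatives ranged from 2.59e-07 to 0.0506.

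The changes of the lines overlapped. Among 13366 genes tested in both, 1220 were higher in both (683 by chance, Fisher's exact odds ratio 3.32) and 1355 lower in both (718 by chance, odds ratio 3.98), while 297 rose in MDA-MB-231 and fell in MCF7 and 321 did the reverse (708 and 692 by chance). Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.368 and a Spearman rho of 0.348.

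The response differed between the lines for 4189 of 17257 genes by edgeR's interaction test. The difference (MDA-MB-231 minus MCF7) was positive for 2132 of them and negative for 2057. Each line's own fit tested fewer genes, and 13366 were tested in both. Some of the 4189, such as MMP1 and CEACAM5, had next to no counts in a line, and how many was not counted. The genes whose response to serine starvation differs between the lines numbered 2020 at a log2 fold change of at least 1, and 6842 without the MDA-MB-231 libraries +Ser 3 and -Ser 1, which stood apart. With the deposited TPM the difference was positive for 31.8% of the calls, against 50.9% here. Among the lists, mitosis fell further in MDA-MB-231 (median difference -0.90, 21 of 30 lower, adjusted over the list alone 23, camera adjusted p 1.11e-16). Interferon-stimulated genes (-1.42, 13 of 23 lower, adjusted over the list alone 14, camera adjusted p 3.4e-09) and p53 targets (-0.76, 13 lower and 3 higher of 22, adjusted over the list alone 18, camera adjusted p 1.45e-05) rose in MCF7 alone among the lines' called lists. These 3 lists kept their calls with an estimated correlation (adjusted p 0.018, 0.018 and 0.0308). ATF4 targets (0.51, camera adjusted p 4.39e-06, estimated 0.111) and autophagy (0.49, 4.37e-05, estimated 0.297) had larger responses in MDA-MB-231 and lost their calls with it. The other 5 of the 10 called lists were transporters, chaperones, purine and pyrimidine synthesis, basal markers and mitochondrially encoded mRNAs, with camera adjusted p-values of 0.0296 to 0.0441. With an estimated correlation these 5 lost their calls (0.193 to 0.69), and each also lost its call without at least 1 single library.

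**Figure D3:**
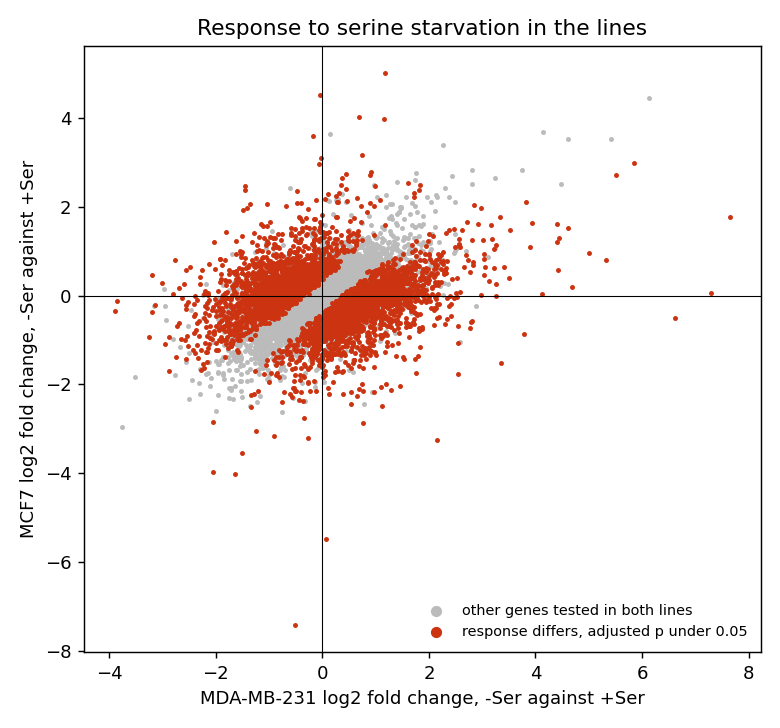
Log2 fold changes (-Ser against +Ser) in MDA-MB-231 and MCF7 for 13366 genes tested in both lines, in red where the responses differed at an edgeR adjusted p under 0.05. Pearson's r across genes was 0.368.

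Of the serine genes, PHGDH responded more in MCF7 (difference -1.08) and SHMT2 more in MDA-MB-231 (0.49). Among genes at a mean of at least 5 CPM, the largest positive differences (MDA-MB-231 minus MCF7) were those of HMCN1, MMP1, YOD1, IL24 and CTH. The largest negative ones were those of CEACAM5, CTNND2, CACNG4, CCBE1 and LONRF3. The sign is that of the difference, not of the change in a line. CTH rose from 6.84 to 94.1 CPM in MDA-MB-231 and fell from 4.22 to 2.34 in MCF7, a log2 difference of 4.64 with an SE of 0.30 and an edgeR adjusted p of 2.32e-06. The other 9 had a group at a mean of 3 counts or fewer per library, so no fold of the difference is given. YOD1 fell in both lines, from 58.7 to 40.8 CPM in MDA-MB-231 and from 0.968 to 0 in MCF7. CACNG4 also fell in both, from 275 to 171 CPM in MCF7 and from 0.265 to 0 in MDA-MB-231. LONRF3 was not called in MDA-MB-231 (edgeR adjusted p 0.927). YOD1 and CACNG4 changed direction under the deposited TPM, and LONRF3 lost its call there. CEACAM5 had 14 counts in MDA-MB-231 +Ser 1 and 0 in the other +Ser libraries. Without that library the log2 fold change of CEACAM5 between the lines' responses had an adjusted p of 0.75, and the log2 fold change of CTNND2 between the lines' responses one of 0.157. The other alternatives gave adjusted p-values from 0.000551 for CEACAM5 and from 0.00132 for CTNND2. MMP1 and CCBE1 lost their calls without several single libraries, at adjusted p-values of up to 0.229 for the log2 fold change of MMP1 between the lines' responses and 0.118 for the log2 fold change of CCBE1 between the lines' responses.

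In +Ser medium the lines differed for 13204 of 17257 genes (edgeR), 6332 higher and 6872 lower in MDA-MB-231, with a median log2 fold change of -0.11. Line and any sequencing batch cannot be told apart in this comparison. With library size only that median was -0.39 and 38.9% of calls were higher, against 48.0% here, so levels are relative to that choice. All 15 luminal markers were lower (median -5.08, camera adjusted p 1.11e-30). Of the basal and mesenchymal markers 15 of 16 were higher (median 6.30, camera adjusted p 2.85e-19). CDH1, a luminal member, was at 0.514 and 808 CPM, and VIM, of the basal and mesenchymal list, at 3172 and 1.59. Other luminal members named were AGR2, EPCAM, GATA3, TFF1 and KRT8. Other members named from the basal and mesenchymal list were FOSL1, CD44, CAV1, SERPINE1 and CAV2. Its keratins KRT5, KRT14 and KRT17 were not among the named members. PSAT1 was at 123 ± 20.2 CPM in MDA-MB-231 and 0.145 ± 0.129 in MCF7. PSPH and SHMT2 were higher in MDA-MB-231 (log2 0.99 and 0.87) and PHGDH and SHMT1 lower (-0.87 and -0.99).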

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

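Tests chosen only after seeing the data were those with length and GC trends removed, on exchanged labels and on depth. So were the use of the shared fit to compare the calls of the lines, and the tests of explanations for the p53, interferon and mitosis lists. The interaction tests of those lists, also with an estimated correlation, were set before their results were seen. The same holds for the split counts, the shared fit itself and the bound on the spread with those trends removed.

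Differences between the lines in their response to serine starvation were the main pattern: 4189 genes and 10 lists passed the interaction test. The genes include some with next to no counts in a line, such as MMP1 in MCF7. The list medians of the difference (MDA-MB-231 minus MCF7) were 0.51 for ATF4 targets, -0.13 for amino acid transporters, 0.39 for endoplasmic reticulum chaperones, -0.76 for p53 targets, -0.90 for mitosis, -0.39 for purine and pyrimidine synthesis, -1.42 for interferon-stimulated genes, 0.49 for autophagy, -0.78 for basal markers and 1.11 for mitochondrially encoded mRNAs. Of these the chaperones, transporters, purine and pyrimidine, basal and mitochondrial lists had camera adjusted p-values of 0.0296 to 0.0441, and estimated-correlation values of 0.193 to 0.69. ATF4 targets (0.111) and autophagy (0.297) also lost their calls with an estimated correlation, so 3 of the 10 lists kept them. Among single genes, PHGDH differed by -1.08, SHMT2 by 0.49 and CTH by 4.64. The other named genes, each with a group at a mean of 3 counts or fewer per library, had edgeR adjusted p-values of 1.3e-05 (HMCN1), 0.0482 (MMP1), 0.000162 (YOD1), 0.00191 (IL24), 0.0138 (CEACAM5), 0.0125 (CTNND2), 0.00177 (CACNG4), 0.0327 (CCBE1) and 0.0017 (LONRF3). Of the 205 genes named for either line, 116 differed, where 24.3% of all 17257 tested genes did. Apart from the serine genes, they were picked from these data by fold change or p within a line. The count is therefore not a result about them as a group.

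Other splits of the libraries were counted for each test. For the interaction, 80 of 200 splits of the serine labels within each line were drawn, and 2 called at least 4189 genes, the real one included; the higher one, with 7152, kept both lines' groups and exchanged the MCF7 labels, so it adds the responses rather than subtracting them. The 66 drawn splits that kept neither line's groups called 0 to 1 genes, as did the other splits within a line, so this count speaks to any response at all and does not exclude chance for the difference between the lines. Drawn splits that kept the groups of MDA-MB-231 alone called 1419 to 2682 genes, and those that kept the groups of MCF7 alone 108 to 623. For the 10 interaction lists chance cannot be excluded: 19 of the 80 splits called at least 10 lists, up to 17, and even splits that kept neither line's groups called up to 12. With an estimated correlation 3 lists were called and 2 of 80 splits gave as many, the real one included. The higher one, with 11, is again the split that exchanged the MCF7 labels. Splits that kept neither line's groups called 0 lists in this way. This count too therefore speaks to any response at all and does not exclude chance for the difference between the lines. The overlap of 2575 genes was reached by 1 of 100 pairs of splits, the real one, with 618 next, but the other splits of a line called at most 1 gene. Pairs of them had next to nothing to share, and the 618 is the real pair with the labels of a line exchanged, so this count adds nothing to those within a line. Within a line 10 splits cannot give a share under 0.05. In MDA-MB-231, 1 split in 10 reached 5345 genes (highest other 1) and 14 lists (highest other 10); in MCF7, 1 reached 8228 genes (0) and 18 lists (12). In +Ser medium 1 of 10 reached 13204 genes (0). Camera with a preset correlation called 7 to 12 lists in the other splits of a line, and 0 with an estimated correlation, so a preset call alone is weak evidence for a list.

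The p53, interferon and mitosis lists responded differently in the lines. With length and GC trends removed, the median differences were -0.94 for p53, -1.35 for interferon and -0.78 for mitosis, which argues against those trends as the cause. Without the 2 MDA-MB-231 libraries that stood apart, they were -0.71, -1.45 and -0.96, which argues against those libraries. The largest camera adjusted p at the preset correlation was 1.25e-05 with the trends removed and 1.82e-05 without the libraries. These settings were not rerun with an estimated correlation, so those p-values alone are weak evidence. Another scaling moved the median of all genes by at most 0.18 on the log2 scale, less than the smallest of the list medians, so the choice among these scalings does not account for them. Each of them is relative within a library, so a change in total RNA per cell could not be seen. MDA-MB-231 carries a mutant p53 and MCF7 a normal one, which may contribute to the p53 list; that difference was not tested.

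The MDA-MB-231 libraries spread more than those of MCF7. With length and GC trends removed the ratio of their coefficients of variation was 2.37 against 2.76 before, so the trends may account for part but not all of it. Exchanged labels of +Ser 3 and -Ser 1 are argued against by the ATF4 targets, whose mean log2 CPM was 2.04 higher in the lowest -Ser library than in the highest +Ser library, where the largest range within a group was 0.50. Lower depth is argued against by a ratio of 1.07 between the mean counts of the lines. RNA quality or handling stays open as untested.

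More genes were called in MCF7 than in MDA-MB-231. With a shared spread, the genes changed by serine starvation in MDA-MB-231 were 1.53 times the genes changed by serine starvation in MCF7 (7286 and 4773), so the larger spread of the MDA-MB-231 libraries may be why fewer were called there, while the depth ratio of 1.07 argues against depth. The shared coefficient of variation was 0.158, below the 0.201 of MDA-MB-231 and above the 0.0729 of MCF7. Such a pooled spread favours calls in MDA-MB-231, so the ratio of 1.53 is not a fair comparison of the lines. The number of calls therefore does not rank the size of the lines' responses.

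Transcripts with no entry in the primary assembly annotation of GENCODE v29 lay outside the gene tests. Of those tested by edgeR, 112 of 6932 changed in MDA-MB-231 and 505 of 7742 in MCF7. Among the largest of these in MCF7, 5 transcripts had the same fold change, SE and mean, so the changed transcripts are not counted as independent; why the values are identical was not tested.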

How the results depend on the processing

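Tests chosen after seeing the data were those with the deposited TPM, with length and GC trends removed, and without the 2 MDA-MB-231 libraries that stood apart.

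The 5345 genes changed by serine starvation in MDA-MB-231 became 2301 at a log2 fold change of at least 1, 3449 with the deposited TPM and 3123 with the replicate block (3110 shared, in the same direction). Leaving out a library gave 3028 to 6070 genes: 3535 without +Ser 2, 3416 without -Ser 2 and 3028 without -Ser 3. The 8228 genes changed by serine starvation in MCF7 became 1458 at a log2 fold change of at least 1 and 4773 with all 4 groups in a shared fit, where the larger spread of MDA-MB-231 enters, and 7471 to 7700 without a library. The 4189 genes whose response to serine starvation differs between the lines became 2020 at a log2 fold change of at least 1, 2437 with the replicate block and 6842 without the 2 libraries that stood apart, and ranged from 3133 to 5751 without a library. The overlap of the 2 lines' changed genes went from 2575 to 355 at a log2 fold change of at least 1. The genes that differ between MDA-MB-231 and MCF7 in serine-containing medium numbered 12671 to 13346 without a library and stayed within 1.5 times its main count in every alternative run. Apart from the stricter thresholds and the shared fit, the cause was not tested.

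With an estimated correlation the lists called were 3 of 14 in MDA-MB-231, 11 of 18 in MCF7 and 3 of 10 between the lines. Without a library they numbered 12 to 14, 18 and 7 to 10, and with the block 14, 18 and 7. Lists were retested with DESeq2 size factors, the block, fry, an estimated correlation, the trends removed, and libraries left out. In these tests no called list changed direction. Lists were not tested with the deposited TPM, where the luminal and chaperone medians in MCF7 changed sign. Of 270 called results for named genes, 2 changed direction, both with the deposited TPM. The log2 fold change of YOD1 between the lines' responses went to -0.31 (limma adjusted p 0.427, where the others were positive and gave 3.29e-06 to 0.00858). The log2 fold change of CACNG4 between the lines' responses went to 0.46 (0.0469, where the others were negative and gave 0.00128 to 0.0144). The cause was not tested. Across alternatives 90 named-gene values lost their call and 3824 kept it.

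Replicate numbers did not pair the samples: the correlations of same-numbered deviations were -0.44, 0.08 and -0.19 in MDA-MB-231 and 0.03, 0.02 and 0.04 in MCF7. In MCF7 every -Ser library correlated best with its own number, as a hint from the data only, and in MDA-MB-231 not. Depth limits genes at a few counts per library, such as PSAT1 in MCF7.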

Other observations

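The genes in this part were chosen after their values were seen, and no explanation was tested for them.

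Opposite responses, called in each line and in the interaction with at least 5 CPM in a group of each line, were seen for 530 genes, 248 rising in MDA-MB-231 and falling in MCF7 and 282 the reverse. TGM2 fell from 1038 to 361 CPM in MDA-MB-231 (log2 -1.51) and rose from 51.6 to 130 in MCF7 (1.34). FTL rose from 1150 ± 387 (SD) to 4841 ± 1630 CPM in MDA-MB-231 (2.09) and fell from 296 to 234 in MCF7 (-0.33). The other iron storage gene looked at, FTH1, rose in both lines (2.05 and 0.76).

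Of 8 alpha and beta tubulin genes with a mean of at least 5 CPM in each line, 5 were lower and 0 higher in MDA-MB-231 (median log2 fold change -0.92), and all 8 were lower in MCF7 (-1.38). TUBA1B went from 2003 to 859 CPM in MDA-MB-231 (log2 -1.21) and from 1800 to 408 in MCF7 (-2.14), a difference of 0.92 with an edgeR adjusted p of 0.00614. TUBB4B had log2 fold changes of -0.87 and -1.56, and neither gene changed sign under another scaling or the deposited TPM.

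Of the transsulfuration enzymes, CBS was at 0.107 and 0.168 CPM in MDA-MB-231 and rose from 64.9 to 210 CPM in MCF7 (log2 1.69), whereas CTH rose in MDA-MB-231 and fell in MCF7. CBS was too low to be tested in MDA-MB-231, and its difference between the lines was not called (edgeR adjusted p 0.351).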
